A study of Mus musculus with 2 samples.

How the data were processed

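The data were 2 Affymetrix expression arrays of mouse AC61 cells, each hybridised with biotin-labelled total RNA. Cells had been infected with a retrovirus made from the vector pLXSB or from the same vector carrying Rb, had been selected in blasticidin for 36 h, and were frozen 72 h after infection, per the labels and the design text. There was 1 array in each group. No array was a replicate of another, so no test, standard deviation between cultures or p-value was computed.

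The deposited values were linear signal intensity values, 1 for each of 45101 probe sets on each array, of which 64 were manufacturer's control probe sets. The labels name Kurabo's RNA extraction and Affymetrix's labelling instructions. The summary algorithm, background correction and scanner settings are not given in the sources used here, and neither present and absent calls nor probe-level values were used here. The 2% trimmed mean over all probe sets was 500 in both deposited columns, so the authors' values had already been scaled to a common level. Such scaling fixes the mean of each array and cannot show a change shared by all transcripts.

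Both arrays were brought to the same 2% trimmed mean over the 45037 probe sets without the controls, with factors of 1.00016 and 0.99984. Values under a floor of 70.8 were raised to it. The floor was the mean of the medians of both arrays, and 49.5% of probe sets in the vector array and 50.5% in the Rb array lay above it. The log2 ratio of the Rb array over the vector array was then taken. A ratio with 1 side at the floor is a bound and is given as "at least". A gene was called measured when its probe set lay above the floor on at least 1 array.

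Gene names came from the platform's annotation table, with symbols updated by Entrez identifier to the GRCm38.p6 gene table. Of the probe sets without controls, 34945 listed 1 gene, 932 listed several and 9160 listed none in that table. The current table held the Entrez identifier of 34741 of the first kind. Probe sets that listed several genes or none gave no gene value. The probe set with the highest mean log2 signal stood for its gene, which gave 18194 genes, 10666 of them measured.

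The measure of error within this pair of arrays was the standard deviation of the log2 ratio among probe sets of the same gene, pooled over 5054 genes with more than 1 probe set above the floor on both arrays. It was 0.23 over all levels, 0.33 under 4 times the floor, 0.19 from 4 to 16 times the floor and 0.12 above that. It covers differences between probes and between the hybridisations, not the variation between cultures.

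A gene was counted as higher or lower by a fixed rule of size, a ratio of at least 2-fold. In addition, 22 gene lists were fixed, 9 of them as main lists. The result of 1 list outside the main ones is not reported here. For each list the median log2 ratio of the measured members was set against 10000 random lists of the same size, each member replaced by 1 of the 100 measured genes nearest in mean signal. A list was described as standing apart when its median fell outside the middle 95% of those medians. Genes of a pathway are not independent of each other, so the percentile describes these arrays and is not a test. The lists, the size rule, the floor and most alternatives were chosen before the data were examined. Chosen after were the scaling on the poly-A controls, the centring on genes of similar level, the second probe sets of list members, the lists without some members, and the support by other probe sets.

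The genes named were the 12 with the largest and the 12 with the smallest ratio among genes reaching 4 times the floor on the brighter array, leaving out clone-like symbols, then up to 4 members with the largest absolute ratio in each list, and Rb1, Rbl1, Rbl2, Nras, Gapdh and Actb. Gapdh was read from its control probe sets. Alternatives changed the scaling (deposited values, equal medians, quantile normalization, hybridisation controls, poly-A controls), the floor, the choice of probe set, the size rule and the members used. Deposited values, equal medians and both control scalings differ from the main values by a constant per array. The percentile of a list whose members lie above the floor could hardly change under these. Counts of alternatives given below include them.

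The steps were tested on simulated data, a pair of arrays with the measured levels and with noise taken from the arrays' own ratios, in which 200 genes were changed. The noise was placed in the simulated Rb array alone at first, and 172 of 10796 unchanged measured genes then passed the 2-fold rule. The simulation was changed after that count had been seen, splitting the same noise equally between the arrays, and 4 of 10400 then passed. The number of genes passing by noise alone therefore depends on how noise is modelled. The ratios it was taken from also hold any real differences, and neither count is used as a false-call rate. Of 67 genes changed by 2.5-fold, 98.5% passed with the first placement and 97.0% with the second. All 66 genes changed by 4-fold and none of 67 changed by 1.5-fold passed with either. The changed genes were drawn only from those with a mean level over 4 times the floor, and all probe sets of a gene moved together. These shares therefore do not describe dimmer genes or genes whose probe sets disagree. In the real arrays 19 of the 25 genes counted as higher stayed under 4 times the floor. A list shifted by 0.3 had a measured median of 0.26 with the first and 0.28 with the second. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.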

Results

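AC61 mouse cells carrying an empty retroviral vector were compared with AC61 cells carrying the same vector with Rb, the retinoblastoma protein, which binds E2F transcription factors and restrains entry into S phase. The question was which transcripts differed 72 h after infection, following 36 h of selection in blasticidin, an antibiotic that kills cells without a resistance gene. Each group had 1 array, so every difference below is a difference between these 2 arrays and has no replicate check. The labels do not give the tissue of origin of AC61 cells. Precision was limited by the number of arrays, and the only error available was the spread of the log2 ratio between probe sets of the same gene, 0.33 for dim genes, 0.19 at middle levels and 0.12 for bright genes.

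The arrays were closely alike. Over the 21499 probe sets above the floor on both, the log2 signals correlated at r = 0.991 across probe sets, which are not independent replicates. Of 10666 measured genes, 94.6% had log2 ratios within 0.5 of 0, and the median was 0.00. The 3' to 5' signal ratio, a measure of RNA integrity, was 0.801 in the vector array and 0.79 in the Rb array for Gapdh, and 1.243 and 1.25 for beta-actin. The 18 hybridisation control probe sets were on average 1.17-fold brighter in the Rb array, while the 24 poly-A control probe sets had 0.841 of their vector signal there. The 5' probe set of 18S ribosomal RNA read 8419 in the vector array and 2145 in the Rb array, with 961 and 628 for its middle probe set. Scaling on the hybridisation controls would lower every log2 ratio measured on both sides by 0.23 and the median gene to -0.22, so such values between 0 and 0.23 below would change sign on that scale. Scaling on the poly-A controls would do the opposite, raising such ratios by 0.25 and the median gene to 0.25. The median of every reported list with a measured member, including all those below 0, would then be positive, with the sterol list lowest at 0.04. Either scaling moves ratios above the floor by a constant, while ratios with 1 side at the floor move by other amounts. Directions are given relative to the bulk of genes.

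The introduced gene was examined first. Rb1 read 225 in the vector array and 305 in the Rb array, a log2 ratio of 0.44 against a spread between probe sets of 0.33 at that level. Its other probe set lay under the floor on both arrays. The labels do not say whether the introduced Rb was the mouse or the human sequence, nor whether it held the 3' end that such probe sets usually match, so this value neither bears out nor contradicts the label. The related pocket protein genes Rbl1 and Rbl2 had log2 ratios of -0.10 and -0.08. Nras, which encodes a small GTPase, had a log2 ratio of 0.65 at its brightest probe set, from 115 to 181, but -0.02 and -0.06 at the other probe sets. Gapdh lay between 0.03 and 0.05 over its control probe sets, and Actb was at 0.06 at its brightest probe set and -0.28 at the other. The positive values of both become negative on the hybridisation control scale.

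By the 2-fold rule, 25 genes were higher and 10 were lower in the Rb array. Most of the higher ones were dim. In 19 of the 25 the brighter array stayed under 4 times the floor, and in 11 the vector array was at the floor, so that the ratio is a bound. Of the 9 higher genes with another measured probe set, 7 had none that reached 1.5-fold in the same direction. The 10 lower genes included 7 that reached 4 times the floor. Only 1 of the 10, Mycn, had other measured probe sets, and none of these was lower by 1.5-fold. With 1 array per group, whether these counts exceed noise was not tested. They depend on the floor, with 731 higher and 395 lower at a floor at the 25th percentile. They also depend on scaling, with 7 higher and 29 lower on the hybridisation controls and 89 higher and 6 lower on the poly-A controls.

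Among the genes that reached 4 times the floor on the brighter array, the largest ratios belonged to Clcn5, Ifi27l2a and Helb. Clcn5, a chloride transporter gene, read 560 and 1545 on the vector and Rb arrays, a log2 ratio of 1.46, but its other 3 measured probe sets lay between -0.35 and 0.26. Ifi27l2a, an interferon-induced gene, read 2124 and 5599, a ratio of 2.64-fold against a spread of 0.12 on the log2 scale at that level. Helb, a DNA helicase gene, was 2.24-fold higher at 1 probe set and lay between -0.30 and 0.05 at the others. Ces5a, Odf2l and Il17re were 2.20-fold, 2.12-fold and 2.07-fold higher, and the other measured probe set of Odf2l pointed the opposite way at -0.71. The remaining probe sets of Ces5a and Il17re lay under the floor on both arrays, as did those of Agrn and Psmb8, listed next. Ranks below 2-fold went to Agrn, the gene of the matrix protein agrin, at 1.96-fold, Ift172 at 1.95-fold, Psmb8 at 1.93-fold, Fance at 1.92-fold, H2-K1 at 1.91-fold and Rab26os at 1.91-fold, although the other measured probe set of Fance was at -0.10. Among dimmer genes Tgfb2, a growth factor gene named after its values were seen, was 2.80-fold higher (99.3 and 278). Its other 3 measured probe sets lay between 0.14 and 1.08. Egr2, a transcription factor gene, was 2.72-fold higher.

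On the lower side Mycn, a proto-oncogene transcription factor, stood alone. Its brightest probe set read 10405 in the vector array and 722 in the Rb array, 14.4-fold lower, while the other measured Mycn probe sets had log2 ratios of 0.20 and 0.28, so the arrays do not give a consistent direction for the gene. Susd5 was at least 4.25-fold lower, and its other probe set lay under the floor on both arrays. Rps27, a ribosomal protein gene with near-identical copies in the genome, was 2.60-fold lower. Lsm7, a component of the RNA-binding Lsm ring, was 2.19-fold lower. Tagln, the gene of the actin-binding protein transgelin, was 2.27-fold lower (324 and 143) and Mgp, the gene of matrix Gla protein, was 2.20-fold lower (387 and 176). Acy1, Mmp10, Ttf1, Dagla, Lnx1 and Cd1d1 followed, between 1.95-fold and 1.72-fold lower, but the other measured probe sets of Ttf1, Cd1d1 and Lnx1 were at 0.12, -0.02 and -0.44.

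**Figure D1:**
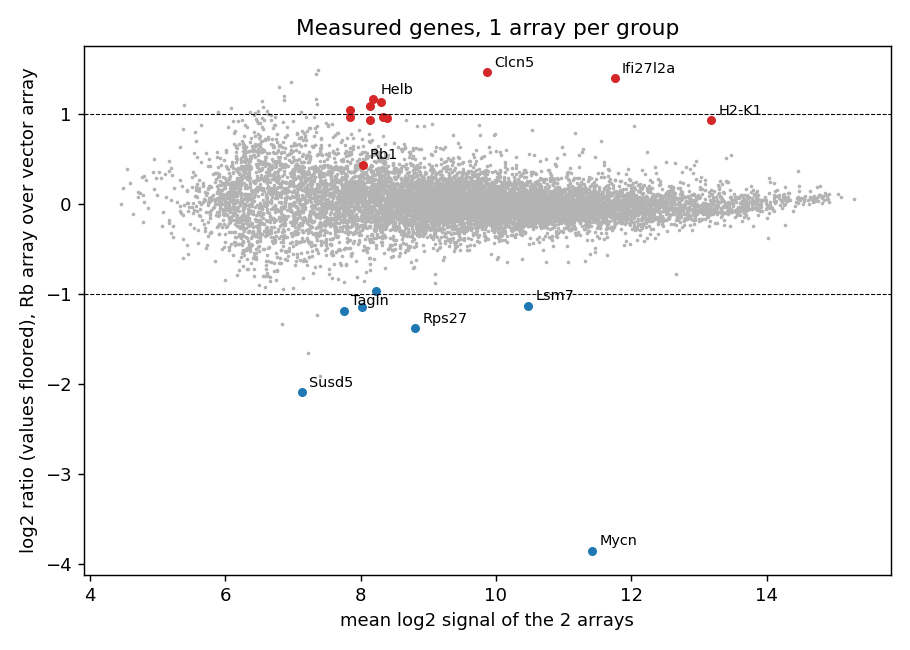
Log2 ratio of the Rb array over the vector array after flooring (vertical axis) against the mean log2 signal of both arrays (horizontal axis) for the 10666 measured genes, 1 point per gene. Dashed lines mark 2-fold, and coloured points are genes named by the fixed rule, with Rb1. Mycn lies at -3.85 on the strength of 1 probe set, and Ifi27l2a and H2-K1 stand out at high signal.

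Interferon response genes, a list that mixes targets of different interferon types, were higher in the Rb array as a group. Of 51 measured members, 46 had a ratio above 0 and 5 below, with a median log2 ratio of 0.35, or 1.28-fold. No random list matched on signal reached this median. Only Ifi27l2a passed the 2-fold rule, and none was lower by 2-fold. The next members were genes of antigen presentation. Psmb8, a subunit of the immunoproteasome, read 241 and 465. Tap1, which carries peptides into the endoplasmic reticulum, read 391 and 722. H2-K1, a class I heavy chain, read 6720 and 12823, with log2 ratios from 0.63 to 2.25 at its other 3 probe sets, although near-identical class I genes can share its signal. The list lay above the middle 95% of random lists under all 14 alternatives. These include scalings by a constant per array, which could hardly have changed its place. Its median was 0.12 with scaling on the hybridisation controls and 0.60 on the poly-A controls.

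Genes of mevalonate and sterol synthesis were lower in the Rb array relative to the bulk of genes. Of 30 measured members, 25 had a ratio below 0 and 5 above, with a median log2 ratio of -0.21, or 1.15-fold lower. No random list had a median this low, though none of the members passed the 2-fold rule. Sqle, the squalene epoxidase gene, read 5377 and 4040, and Lss, lanosterol synthase, read 1282 and 974. Npc1, which moves cholesterol out of lysosomes, read 710 and 525, and Tm7sf2, a sterol reductase gene, 152 and 115. The list stayed below the 2.5th percentile under all 13 alternatives, although scalings by a constant per array could hardly have moved it.

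For genes of protein prenylation and CAAX processing the median over 19 measured members was -0.07, at the 7.1th percentile, with 12 members below 0 and 7 above. This lay inside the random range, but the list fell below it with quantile normalization, at the 2.4th percentile, and with centring, at the 1.59th. The second probe sets of the 7 members that have one had a median of 0.07. Fdps, farnesyl diphosphate synthase, which also belongs to the sterol list, read 8450 and 6892, a log2 ratio of -0.29. Fntb, the beta subunit of farnesyltransferase, lay the other way at 0.26, and Pcyox1 and Rabggta were at -0.28 and -0.23. The other measured probe sets of Pcyox1 were at -0.10 and -0.01.

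Cell cycle genes differed little. For E2F targets and DNA replication genes the median over 62 measured members was -0.07, or 1.05-fold lower, with 47 members below 0 and 15 above. It lay at the 0.64th percentile of random lists, whose medians centred on -0.0248, and remained under the 2.5th in all 13 alternatives. Scalings by a constant per array could hardly move it and left it at 0.64. No member reached 2-fold. The largest differences were in Uhrf1, a maintenance methylation factor, at -0.29, Ccne2, cyclin E2, at -0.27, and Rpa2 and Fen1, which act at replication forks, at -0.22 each. The other probe set of Uhrf1 was at 0.00. For G2/M and mitosis genes the median over 60 measured members was -0.05, at the 9.95th percentile, with Spc24 at -0.32 and Mad2l1, a spindle checkpoint gene, at -0.22. The G1 control list had a median of -0.07 over 39 members, at the 1.24th percentile, but lay inside the middle 95% of random lists in 6 of 14 alternatives. It shares E2f1, E2f2, E2f3, E2f7, E2f8, Rbl1, Ccne1 and Ccne2 with the E2F list, so these lists are not separate observations. Apart from Mycn, the largest differences in the G1 control list were in Ccnd2, cyclin D2, at -0.55 and Id2 at 0.51. The other 4 measured probe sets of Ccnd2 lay between -0.67 and -0.04, and that of Id2 at 0.19.

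The p53 target list had a median of 0.10 over 37 measured members, at the 98.4th percentile, with 24 above 0 and 13 below, and no member at 2-fold. It lay inside the random range in 4 of 14 alternatives, namely quantile normalization, the median over probe sets, centring and the second probe sets. The last had a median of -0.05 over the 17 members that have one. The leading members were Tap1, which also belongs to the interferon list, Btg2 at 0.72 (-0.29 at its other probe set) and Gadd45a, a growth arrest gene, at 0.69, while Ercc5, a DNA repair nuclease gene, was at -0.67. Of the secreted factors of senescent cells, 18 of 34 measured members were above 0 and 16 below, with a median of 0.03 at the 89.9th percentile. The matrix metalloproteinase genes Mmp10 and Mmp3 were lower, at -0.88 and -0.64, and the cytokine genes Lif and Il1b read higher, at 0.62 each, Il1b close to the floor with 72.5 and 111.

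The count of markers above the floor differed between cell types. Of the fibroblast and mesenchymal markers with a probe set, 38 of 41 were measured, against 8 of 38 neuroendocrine and thyroid C cell markers, 0 of 11 thyroid follicular markers, 12 of 32 epithelial, 4 of 27 leukocyte and 4 of 20 endothelial markers. Over all genes with a probe set of their own, 10666 of 18194 were measured. These counts depend on the floor, and with a floor at the 25th percentile they were 41 mesenchymal, 31 neuroendocrine, 25 epithelial, 19 leukocyte and 13 endothelial markers. At that floor 15546 of the 18194 genes were measured, so the contrast between cell types was weaker there. Neuroendocrine markers had a median of 0.12, inside the random range. The mesenchymal list had 27 members above 0 and 11 below, with Tagln at -1.18 and Thy1 at -0.42 the other way from its median of 0.07. That median was at the 99.97th percentile, and lay above the middle 95% of random lists in all 13 alternatives. Its median itself was -0.02 and -0.15 with scaling to equal medians and on the hybridisation controls, which move the median gene as well. Epithelial markers had a median of 0.14, at the 91.5th percentile. Crb3 was at least 2.46-fold higher (0.34 at its other measured probe set) and Epcam was at 0.93, both under 4 times the floor. The other probe set of Epcam read 6.44 and 4.56 on the vector and Rb arrays, under the floor on both. In 9 of 13 alternatives, including all that changed the floor, the epithelial list lay above the middle 95% of random lists. Leukocyte and endothelial markers had medians of 0.17 and -0.06 over 4 genes each, inside the random range. The endothelial median had no settled sign, from -0.29 on the hybridisation controls to 0.43 with second probe sets, and the leukocyte median was -0.06 on the hybridisation controls.

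**Figure D2:**
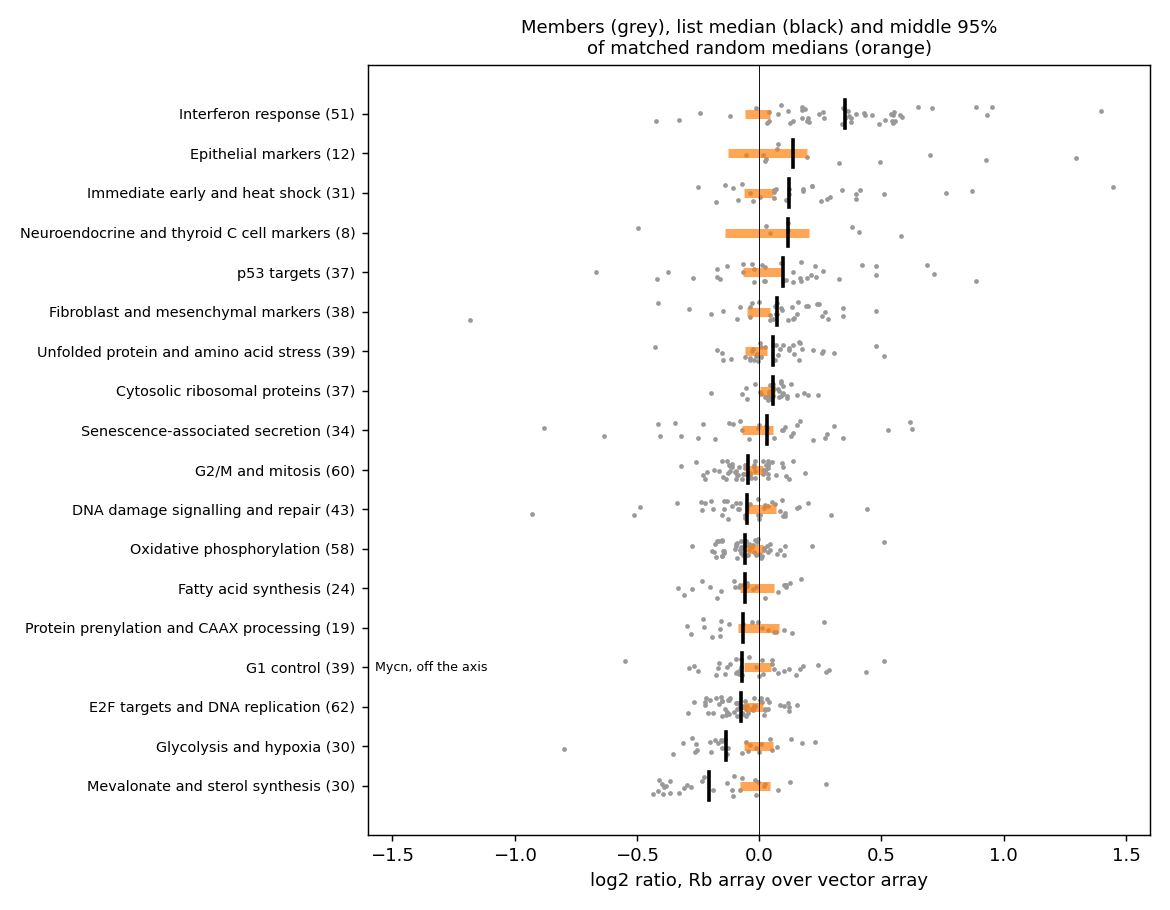
Log2 ratio of the Rb array over the vector array (horizontal axis) for the measured members of each reported list with at least 8 of them (vertical axis, number measured in brackets). Grey points are genes, black bars list medians and orange bars the middle 95% of medians of matched random lists. The interferon list at 0.35 and the sterol list at -0.21 lie farthest from their orange bars, with every value relative to the bulk of genes, and Mycn at -3.85 is off the axis.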

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

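The tests of the interferon, Mycn and sterol patterns below were chosen after those patterns were seen. For the class I and second probe set tests the prediction was written before the reduced medians were computed, though the ratios of single members had been seen.

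Among the 3329 measured probe sets that list several genes or none, 3 were at least 2-fold higher in the Rb array at 4 times the floor or more, and 0 were lower by that rule. Each of the 3 lists 2 genes and is given by its identifier, because it lies outside the gene values of the report. Probe set 1424948_x_at read 1464 and 4379 on the vector and Rb arrays, a log2 ratio of 1.581. Probe set 1429184_at read 579 and 1633, a log2 ratio of 1.4964. Probe set 1449009_at read 932 and 1886, a log2 ratio of 1.0178.

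The interferon response list was higher in the Rb array, with a median log2 ratio of 0.35 over 51 genes. A bias that depends on signal level is argued against by the random lists matched on signal, whose medians centred on -0.0062. Centring on genes of similar level, which gave 0.3376, takes out the same small shift and is not a separate test. Cross-hybridisation among class I and antigen processing genes, as the source of the whole shift, is argued against by its breadth. At least 1.2-fold higher were 29 of the 51 members. The median of 0.302 over the 44 members outside these groups follows from that breadth and could hardly have come out otherwise. Leukocytes in the Rb culture are argued against by their markers, whose median level in the Rb array was 23.42 against 21.76 in the vector array, under the floor of 70.8, with Lyz2 at 29.7 and Tyrobp at 10.7. Of the 27 markers 4 lay above the floor, Cd14 at 1177, Csf1r at 123, Itgb2 at 93.8 and Laptm5 at 84.1, each with a vector value within 1.2-fold. A difference between the cultures other than Rb, such as in density, viral dose or the response to infection, cannot be told apart from an effect of Rb, because each group has 1 array, and an effect of Rb was not tested.

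The brightest Mycn probe set was 14.4-fold lower in the Rb array. A lower level of the whole Mycn transcript was not seen at the other measured Mycn probe sets, with a median log2 ratio of 0.2432 over 2 probe sets. On the vector and Rb arrays 1 of these read 611 and 704 and the other 126 and 154. Both were far dimmer than the 10405 of the brightest probe set in the vector array. They may not report the RNA behind that signal, so they cannot decide this explanation. A copy number difference of the region is argued against by the measured neighbours within 1 Mb in the GRCm38.p6 gene table (Ddx1, Nbas and Cyria), with a median of 0.177. A transcript form or another RNA matched by this probe set alone, or a flaw of 1 array, stays open as well. Only 1 measured probe set of the gene shows a difference of 8-fold or more, and probe-level values were not used here.

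The sterol synthesis list was lower in the Rb array relative to the bulk of genes, with a median log2 ratio of -0.21 over 30 genes. A bias that depends on signal level is argued against by the random lists matched on signal, whose medians centred on -0.0207. Centring, which gave -0.1826, takes out the same small shift and is not a separate test. Errors of single probe sets are argued against by a median of -0.2313 over the second probe sets of the 16 members that have one. A difference between the 2 cultures other than Rb, such as in density or lipid supply, cannot be told apart from an effect of Rb with 1 array per group. Either may account for the difference.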

How the results depend on the processing

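Centring, poly-A scaling, second probe sets and reduced lists were chosen after seeing the data. No replicate could be left out, with 1 array per group, and the thyroid follicular list gave no value. The count of 25 higher genes became 16 with arrays scaled to the same median, 16 after centring on genes of similar level, 7 when scaled on the hybridisation controls, 89 on the poly-A controls, 6 with a floor at 2 times the median, 731 with a floor at the 25th percentile and 1776 with no floor. It was 250 by a size rule of 1.5-fold and 0 by 3-fold. The count of 10 lower genes became 29 on the hybridisation controls, 6 on the poly-A controls, 395 with the floor at the 25th percentile, 1364 with no floor, 105 by 1.5-fold and 4 by 3-fold. Signal over background limits these counts, since lower floors admit dimmer genes.

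Scaling on the hybridisation controls lowered ratios measured on both sides by 0.23 and scaling to equal medians moved the median gene to -0.09. Ratios with 1 side at the floor moved by other amounts. List medians were -0.1659 (equal medians) and -0.2999 (hybridisation controls) for E2F targets, -0.1401 and -0.2741 for G2/M, -0.1632 and -0.299 for G1 control, -0.2995 and -0.4335 for sterol synthesis, -0.1605 and -0.2945 for prenylation, 0.0046 and -0.1294 for p53 targets, -0.0662 and -0.1906 for senescence secretion, 0.2575 and 0.1235 for interferon response, and 0.026 and -0.1081 for neuroendocrine markers. Among lists outside the random range, signs also turned for mesenchymal markers (-0.0201 and -0.1541), the unfolded protein list (-0.0366 and -0.1706) and the early response list (-0.1047 on the hybridisation controls). Scaling on the poly-A controls raised ratios measured on both sides by 0.25. Every reported list then had a positive median. From below 0 came E2F targets (0.1785), G1 control (0.1812), sterol synthesis (0.0449), glycolysis and hypoxia (0.1143), oxidative phosphorylation (0.1936), G2/M (0.2043), prenylation (0.1839), fatty acid synthesis (0.1932), DNA damage signalling (0.1999) and endothelial markers (0.0571). Medians were 0.349 for p53 targets, 0.2782 for senescence secretion, 0.5952 for interferon response and 0.332 for neuroendocrine markers. None of these 3 scalings moved a main list across the bounds of the middle 95% of random lists. That outcome was nearly fixed in advance, since each shifts members and random lists by the same constant above the floor.

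Only part of each list has a second measured probe set, 7 members for prenylation, 17 for p53 targets and 20 for interferon response. With second probe sets the medians were -0.0976 for E2F targets, 0.0168 for G2/M, -0.0389 for G1 control, 0.0665 for prenylation, -0.048 for p53 targets and 0.2266 for interferon response. With the median over probe sets they were -0.0276 for G2/M, -0.0006 for G1 control, 0.0446 for p53 targets and 0.3072 for interferon response. The remaining values were -0.0257 for G2/M after centring, -0.0419 for G1 control without _s_at and _x_at probe sets, and 0.3156 with quantile normalization and 0.302 without class I and antigen processing members for interferon response. Clcn5 was at -0.064 without _s_at and _x_at probe sets, and Mycn at 0.2027 with the median over probe sets. Outside the scalings, the cause was not tested. The interferon, sterol and E2F lists stayed outside the middle 95% of random lists on the same side under every alternative run, 14, 13 and 13 of them. Those that scale each array by a constant could hardly have moved these lists, and lower floors barely touch bright genes. Quantile normalization, the median over probe sets and second probe sets could have moved them, and left them outside that range. The prenylation list fell below it in 2 of 13 and the senescence list lay above it in 1 of 13.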

Other observations

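Glycolysis and hypoxia genes were lower in the Rb array than the bulk of genes, with 22 of 30 measured members below 0 and 8 above. The median log2 ratio was -0.14, below every random list, and it stayed below the middle 95% under all 13 alternatives, with no member at 2-fold. Scaling on the poly-A controls, which raises the median gene to 0.25, put the list's median itself at 0.11. Ankrd37, a hypoxia-induced gene, read 127 and 73.1 on the vector and Rb arrays, and Bnip3, a mitophagy receptor gene, 2137 and 1676. P4ha2, a collagen prolyl hydroxylase gene, was at -0.31 and Bhlhe40 at -0.28. Immediate early and heat shock genes lay the other way, with 23 of 31 measured members above 0, 8 below and a median of 0.12, above every random list. Egr2, an early growth response gene, was 2.72-fold higher from a dim 98.7 with 0.71 at its other probe set, and Egr1 read 3099 and 5656. Dusp5, a MAP kinase phosphatase gene, read 767 and 1301, and Egr3 was at 0.51. The list lay above the middle 95% in all 13 alternatives, although its median itself was -0.10 with scaling on the hybridisation controls, which lowers the median gene to -0.22.

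The unfolded protein and amino acid stress list had a median of 0.06 over 39 members, above the middle 95% of random lists but not after centring or with second probe sets. Oxidative phosphorylation genes had a median of -0.06 over 58 members, below that range but not in the same pair of alternatives. Inside the range lay fatty acid synthesis at -0.06 over 24 members, DNA damage signalling at -0.05 over 43 and ribosomal proteins at 0.06 over 37. The ribosomal median was -0.04 with scaling to equal medians and -0.17 on the hybridisation controls, and the DNA damage median was 0.01 with second probe sets. The fatty acid list fell below it in 2 of 13 alternatives.

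Among the 100 genes with the largest ratios at a mean level over 4 times the floor, 14 belonged to the interferon list, where 0.54 would be there by number alone, and 3 to the early response list, against 0.32. This count was chosen after the ratios were seen.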
